A study of Mus musculus with 4 samples.

How the data were processed

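FOXL2 binding was measured by ChIP-seq in ovaries of CD1 mouse embryos at embryonic day 14.5, with 2 FOXL2 ChIP samples and 2 input samples. Group and replicate number came from the sample titles. The labels' protocols state that the ChIP experiments were independent and used different pools of ovaries, so the replicates are pools of animals. Per the submitters' processing notes, the tools Bowtie 1.2, Picard 1.110, bedtools 2.24.0 and HOMER 4.9 and the genome build mm10 were used. Their roles, parameters and peak threshold, and the way the replicates and inputs were combined, are not given in the sources used here. The authors' deposited values are the start and end positions in bp of 11438 peaks in 1 list for the ChIP samples, with no header, score, height, p-value or strand. All peaks are 300 bp wide with no duplicates, and the smallest distance between centres is 355 bp, so widths carry no information on the strength or breadth of binding. Because the list holds no reads, the depth of the samples is unknown, weak sites cannot be told from strong ones, and a place without a peak may hold binding below the authors' threshold. The threshold and the pooling set how many peaks there are, and so every count of occupied genes.

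Start positions were converted to 1-based coordinates and the centre of each peak was used. Genes came from a RefSeq gene table of assembly GRCm38.p6, the assembly that mm10 denotes, with 49943 genes of all kinds, of which 21887 are protein-coding. That table gives the start, end, kind and transcripts of each gene but no strand or exons, and no genome sequence was used here. The transcription start sites, exons and introns of the planned tests were therefore replaced by gene borders, either end of the gene, and by positions inside or outside genes. Distances were taken to the nearest protein-coding border. The planned tests of sequence motifs in peaks and of motif positions were not run, and neither were alternatives that need GC content, masked repeats, a score or varying widths.

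Peak positions were compared with 1000 random placements of the same number of peaks per chromosome between its first and last annotated gene, assembly gaps included, and p was two-sided with a smallest value of 0.002. Confidence intervals of shares are exact binomial intervals at 95%, and peaks are not fully independent of one another. For the gene lists, fixed before the data were examined, a gene was occupied if a peak centre lay in its body or within 10 kb of either end. Occupancy was compared with 10000 random lists of protein-coding genes of the same size, matched on window length in 20 bins (two-sided permutation p, smallest value 0.0002, Benjamini-Hochberg adjustment over 26 lists, threshold 0.05). The adjustment was made within each setting and does not cover the number of settings tried. Lists covered ovarian, testicular and early gonadal somatic cells, other cell types of the gonad and its surroundings, unrelated tissues, housekeeping genes, signalling pathways and gene families. Pairs of lists were compared by Fisher's exact test without their shared genes, with adjustment over 10 comparisons. Chromosome densities were compared by an exact rank test of X among the 19 autosomes, and the correlation of densities by 100000 permutations.

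Named genes followed a rule fixed before the data were examined. It takes up to 12 occupied genes per ovarian, testicular and early gonadal list in order of peak count and then distance, the unoccupied pregranulosa and Sertoli genes, and up to 4 genes of each other list that passed. It adds the 15 genes with the most peaks, the 15 with the most peaks per 10 kb among genes with at least 4, and Foxl2. Ties in peak number were broken by the shorter gene. A part of the rule that asked for the widest peaks did not apply because all widths are equal. A few of the genes that the rule takes are not reported here.

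Alternatives were borders of 5 kb, genes of all kinds, the peak edge in place of the centre, windows of 50 kb, assignment to the nearest border, neighbour distances of 5 and 50 kb, and merging of peaks within 500 bp. Others were added after the data were examined. These were moving each peak by up to 1 Mb, odd and even autosomes apart, peaks per gene, peaks over 1 kb from every border alone, peaks at a gene's own border alone, matching on neighbouring borders, and placement of border peaks at random borders. The tests were first tried on simulated data. With 30% of peaks planted at borders, 30.2% were recovered, and without planting the p was 0.915. Of 960 list tests without planting 2 were called, with the olfactory and vomeronasal receptor lists left out of this count. The pregranulosa list was called in 40 of 40 placements with 14 of its genes planted as occupied, among 21887 genes. In these placements 20.75% of its genes were occupied before planting, whereas lists matched to it averaged 51.8% with the real peaks. The simulation therefore does not show how often such a list would be called at the real share. The computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.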

Results

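FOXL2 is a forkhead transcription factor of the granulosa cell lineage, the somatic cells that support the oocytes of the ovary. Its binding sites were mapped by ChIP-seq, in which DNA fragments bound by a protein are recovered with an antibody and sequenced, in ovaries of CD1 mouse embryos at stage E14.5. The series held 2 FOXL2 ChIP samples and 2 input samples, input being chromatin sequenced without the antibody step. Different pools of ovaries, freed of the adjoining mesonephros, went into the ChIP samples. The values analysed here were the positions of 11438 FOXL2 peaks on build mm10, deposited as a single list for the ChIP samples. Each peak was 300 bp wide, and the peaks together covered 3.43 Mb, or 0.127% of the sequence between the first and last annotated gene of each chromosome. Neighbouring peak centres lay a median of 78.4 kb apart. Of the peaks, 11435 lay on chromosomes 1 to 19, X and Y and were analysed, and 3 lay on other scaffolds. The list gave no score, height or value per replicate, so the read depth is unknown and no peak has a replicate error. The p-values given for peaks and genes therefore measure chance in the placement of peaks or in the choice of genes. The intervals treat peaks as independent draws. None of them measures the spread between pools of ovaries.

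The first question was where in the genome FOXL2 was bound. FOXL2 peaks were concentrated at the ends of protein-coding genes. Within 1 kb of a gene border, meaning either end of the annotated gene, lay 7245 peaks, which is 63.4% of them (exact 95% confidence interval 62.5 to 64.2%). Random placement of the same number of peaks on the same chromosomes put 3.16% there (95% of placements 2.86 to 3.45%), so the share was 20.0 times that of chance. Peaks deeper inside genes numbered 2522 (22.1% against 38.7% placed, 0.57 times chance), and 1668 lay between genes (14.6% against 58.1%, 0.25 times chance). The median distance from a peak centre to the nearest border was 0.452 kb against 47.6 kb for placed peaks. Within 10 kb of a border lay 79.3% of peaks against 21.8% placed, 3.64 times chance, and within 100 kb 95.5% against 64.3%. Each of these differences had a two-sided permutation p of 0.002, the smallest that 1000 placements can give. The size of the first ratio depended on the definitions. It was 5.75 for borders of 5 kb, 10.7 when genes of all kinds were used, and 12.6 when each peak was moved by up to 1 Mb, a setting that also lowered the ratio within 10 kb to 2.43.

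At the borders, peaks sat mostly just inside the gene. Of the 7245 border peaks, 5915 (81.6%) had their centre inside the gene and 1330 outside, with a median distance to the border of 230 bp. The fullest 100 bp interval, from 100 to 200 bp inside the gene, held 1575 peaks, and the fullest outside, the 100 bp next to the border, held 399. Genes with a single listed transcript had 1865 border peaks at a median of 145 bp inside (bootstrap 95% interval 137 to 153 bp). Genes with 5 or more transcripts had 2604 at a median of 235 bp inside (221 to 252 bp). Among 16853 genes at least 5 kb long, 6821 had a peak at a single border and 77 had peaks at both. From the occupied shares of lower-coordinate and of higher-coordinate borders, 722 would be expected if these were independent. Each of those sets mixes both directions of transcription, so unequal occupancy of gene starts and ends could also give few genes with both. Strand was not used here, so which of the borders is the transcription start site was not determined. Of the 4190 peaks over 1 kb from every protein-coding border, 480 (11.5%) lay within 1 kb of the border of a long noncoding RNA gene, against 1.83% for placed peaks (permutation p = 0.00995, two-sided, 200 placements).

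**Figure D1:**
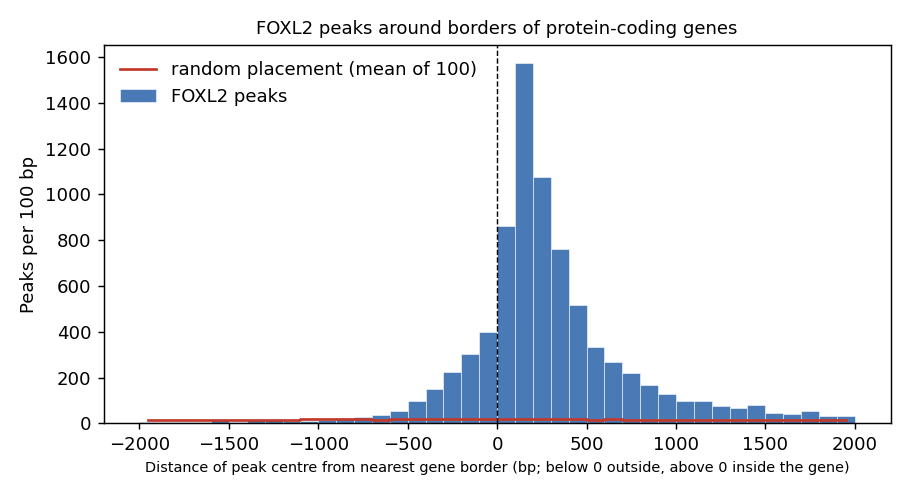
Number of FOXL2 peaks per 100 bp (vertical axis) by distance of the peak centre from the nearest protein-coding gene border in bp (horizontal axis; values above 0 lie inside the gene), with the mean of random placements as a line. The fullest interval, 100 to 200 bp inside the gene, holds 1575 peaks.

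The next question was whether genes of the ovarian and testicular cell types carried FOXL2 peaks. A gene was counted as occupied when a peak centre lay in its body or within 10 kb of either end. Of 21887 protein-coding genes, 10859 (49.6%) were occupied, against 21.9% under random placement. In the pregranulosa list, genes of the fetal supporting cells of the ovary, 14 of 20 genes (70.0%) were occupied. Length-matched random lists averaged 51.8%, a ratio of 1.35, and the difference did not pass the test (permutation adjusted p = 0.350). Genes active in the early gonad of either sex were occupied in 17 of 22 cases (77.3% against 55.9%, ratio 1.38, permutation adjusted p = 0.212). For later granulosa and follicle genes the figures were 13 of 24 (54.2% against 58.7%, ratio 0.92, permutation adjusted p = 0.842). Sertoli cell genes, which mark the supporting cells of the testis, were occupied in 10 of 26 cases (38.5% against 48.7%, ratio 0.79, permutation adjusted p = 0.534).

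Peaks away from gene borders were also counted alone. This class still holds the edge of the border excess, with 96 peaks 1000 to 1100 bp inside genes against 16.6 placed. With peaks over 1 kb from every protein-coding border alone, 10 of 20 pregranulosa genes (50%) were occupied against 15.1% in matched lists, a ratio of 3.31 (permutation adjusted p = 0.0017). The Sox list also passed, with 8 of 19 genes and a ratio of 3.75 (permutation adjusted p = 0.0065), and the Gata list had 4 of 6 and a ratio of 4.9 without passing (permutation adjusted p = 0.0551). The ratio of the Sertoli list was 1.25 (4 of 26 genes, permutation adjusted p = 0.975), that of later granulosa genes 1.88 (9 of 24, adjusted p = 0.142) and that of early gonad genes 1.97 (8 of 22, adjusted p = 0.142). A peak within 1 kb of a gene's own border was counted for it only where no other protein-coding border was nearer. For such own-border peaks the pregranulosa ratio was 0.94 (6 of 20, permutation adjusted p = 1). Later granulosa genes were occupied less often than matched genes (3 of 24, ratio 0.34, permutation adjusted p = 0.0483). Both peak classes were separated after the data were examined. The pregranulosa list also passed with peaks assigned to the nearest border at any distance (ratio 1.87, permutation adjusted p = 0.0043) and with matching on neighbouring borders (1.68, adjusted p = 0.0438). It did not pass in a 50 kb window (1.21, permutation adjusted p = 0.619) or within 5 kb of a border (1.36, adjusted p = 0.369). Adjustment covered the lists of a single setting and not the number of settings, and 0.0438 and 0.0483 lie close to the threshold. Set directly against each other without their shared gene, pregranulosa and Sertoli genes were occupied in 14 of 19 and 10 of 25 cases (Fisher's exact p = 0.0354). For peaks away from borders the counts were 10 of 19 and 4 of 25 (Fisher's exact p = 0.0204). Against other lists, peaks away from borders gave 10 of 20 pregranulosa genes and 3 of 20 housekeeping genes (Fisher's exact p = 0.0407), 10 of 20 and 8 of 30 germ cell genes (p = 0.134), and 7 of 17 and 6 of 21 later granulosa genes (p = 0.502). The smallest p among these comparisons was that of early gonad against Sertoli genes for all peaks, with 16 of 21 and 9 of 25 occupied (Fisher's exact p = 0.00857), and for peaks away from borders it was 0.107 (8 of 21 and 4 of 25). None of the 10 exact comparisons of lists passed adjustment (adjusted p = 0.0857 to 0.763).

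Among pregranulosa genes, Cdkn1b, a cyclin-dependent kinase inhibitor, had 3 peaks, 287, 1928 and 2873 bp outside the gene. Rspo1, a secreted activator of WNT signalling needed for ovary development, had 2 peaks outside the gene on chromosome 4, at 125010336 to 125010635 and 125017714 to 125018013, which are 1383 and 8761 bp from its border. Runx1, a transcription factor of the supporting cells, had 2 peaks inside the gene on chromosome 16, at 92605755 to 92606054 and 92697465 to 92697764. Kitl, the ligand of the KIT receptor, had a peak 380 bp and another 16218 bp inside the gene. Gata4 had a peak 23916 bp inside the gene and a second that lay nearest to the border of Neil2. Fst, which encodes the activin antagonist follistatin, had a peak 1604 bp inside the gene on chromosome 13, at 114457236 to 114457535. Peaks lay inside the WNT pathway genes Lgr5 (214 bp from the border), Wnt4 (327 bp), Fzd1 (434 bp) and Lef1 (2096 bp), and inside Bmp2 (566 bp) and Sp5 (1319 bp). Foxl2 itself, on chromosome 9 from 98955607 to 98958126, had no peak in its window. The peak nearest to Foxl2 was 15.2 kb away, at 98973139 to 98973438, between Foxl2 and Faim. Irx5 (nearest peak at 25.8 kb), Nkd1 (32.8 kb), Irx3 (112 kb), Msx1 (143 kb) and Nr0b1 (179 kb) were also without a peak.

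Among Sertoli genes, Dmrt1, a transcription factor that maintains testicular cell identity, had a peak 415 bp inside the gene. Aard (12 bp outside), Vnn1 (168 bp inside), Fgfr2 (1017 bp), Erbb4 (1475 bp) and Fgf9 (5660 bp) also had peaks in or next to the gene. The 2 peaks counted for Amh, the anti-Müllerian hormone gene, lay at the borders of Plekhj1 and Sf3a2. Those of Dhh were nearest to Kmt2d and Rhebl1, and the peak nearest to Rhebl1 lay 390 bp outside Dhh. The peak counted for Hsd17b1 lay at Naglu, and that of Col9a3 at Ogfr. Sox9, the main transcription factor of Sertoli cell differentiation, had no peak in its window. The peak nearest to Sox9 lay 31.4 kb from the gene on chromosome 11, at 112818959 to 112819258. The Sertoli genes Clu, Inhbb, Cbln4, Mro, Cst9, Hsd17b3, Sox10, Cyp26b1, Tesc, Ptgds, Pdgfa, Sox8, Nr0b1, Gdnf and the Y-linked Sry were without a peak as well. Sry counts as unoccupied among the 26 Sertoli genes, although tissue labelled XX should lack it. The nearest peak was 14.7 kb from Clu and 228 kb from Gdnf.

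**Figure D2:**
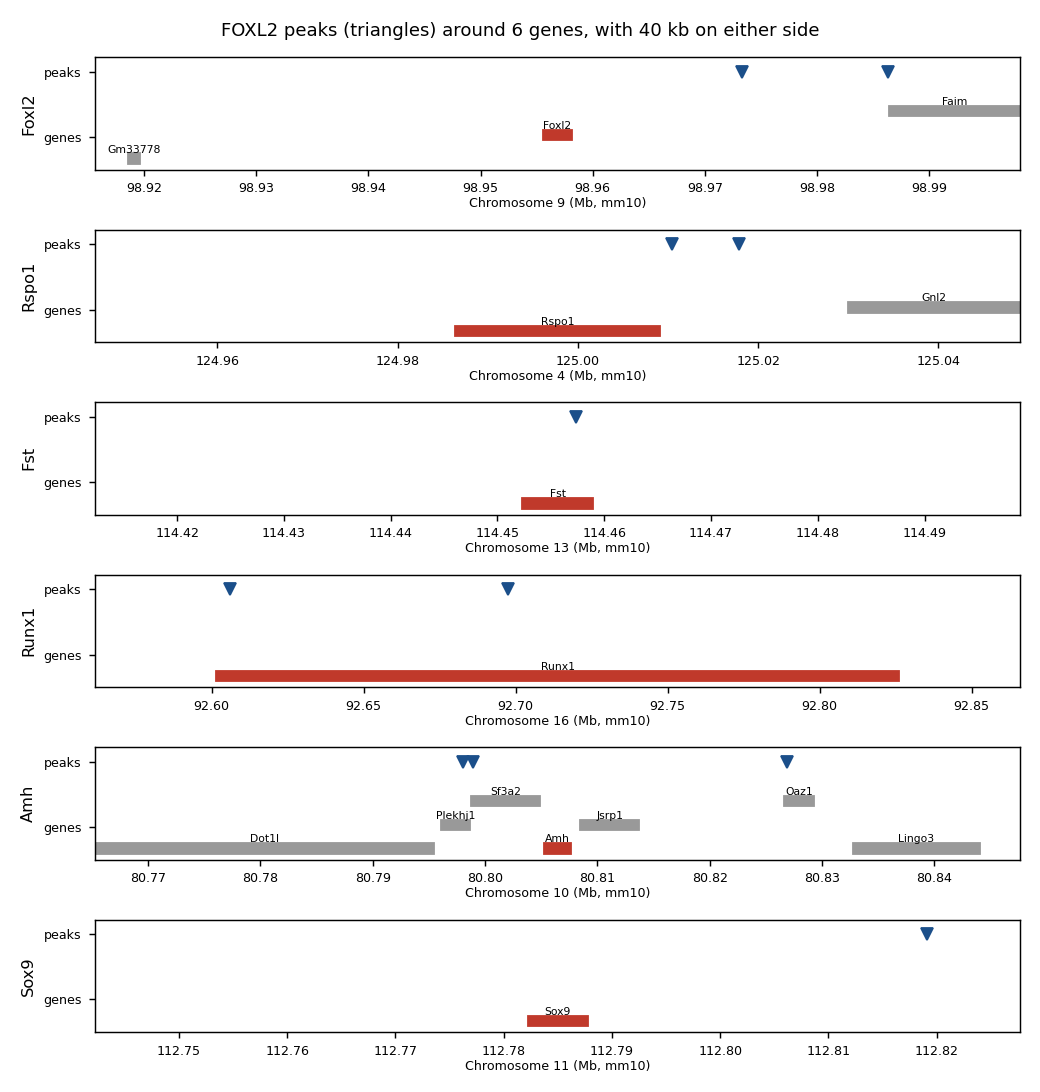
FOXL2 peaks (triangles) and protein-coding genes (bars, the named gene in red) around Foxl2, Rspo1, Fst, Runx1, Amh and Sox9, with 40 kb on either side; the horizontal axes give mm10 positions in Mb. There are 2 peaks in the Foxl2 region, both outside the gene, and 1 in the Sox9 region.

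In the later granulosa list, Greb1, an estrogen-responsive gene, had 4 peaks, 3 of them inside the gene and 1 at the border of E2f6. Npr2, the receptor of C-type natriuretic peptide, had 2 peaks inside the gene, 2617 and 3305 bp from the border, and another at Hint2. Foxo1 had peaks on both sides of its border, 413 bp outside and 178 bp inside. Peaks lay inside Bmpr1b (341 bp), Gja1 (1432 bp), the progesterone receptor gene Pgr (2577 bp) and the activin subunit gene Inhba (7766 bp), and outside Foxo3 (1281 bp). The peak counted for Inha lay at the border of Obsl1. Among early gonad genes, Igf1r had 3 peaks, and Six4, Map3k4, Cited2 and Wtap had 2 each. Insr (213 bp), Numb (287 bp) and Cbx2 (399 bp) had a peak inside the gene, and Kdm3a had a peak 290 bp outside.

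Of the 26 lists, housekeeping genes, which are used in every cell, were occupied most. In this list 17 of 20 genes (85.0%) had a peak against 46.5% in matched lists, a ratio of 1.83 (permutation adjusted p = 0.0065). Cell cycle genes were occupied in 21 of 26 cases (80.8% against 51.4%, ratio 1.57, permutation adjusted p = 0.0146). Liver genes were occupied less often than matched genes, in 2 of 20 cases (10% against 49.8%, ratio 0.20, permutation adjusted p = 0.0052). Olfactory receptor genes were occupied in 9 of 1106 cases (0.814% against 14.4%) and vomeronasal receptor genes in 3 of 353 (0.850% against 27.1%). Each had a permutation adjusted p of 0.0026, from the smallest p that 10000 random lists can give. Genes of these lists can share windows, and the lists were left out of the simulated count of false calls. For peaks over 1 kb from every border the housekeeping, cell cycle and liver ratios were 1.56, 2.03 and 0.43 and did not pass (permutation adjusted p = 0.777, 0.184 and 0.777). The liver ratio was 0.90 in a 50 kb window (permutation adjusted p = 0.892).

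Tbp, the TATA-binding protein gene, had a peak 16 bp inside the gene and 2 others at Psmb1 and Pdcd2. Rplp0, a ribosomal protein gene, and Polr2a, which encodes the largest RNA polymerase II subunit, each had 2 peaks, the nearer at 94 and 135 bp outside. Among cell cycle genes, Cdkn2c had 4 peaks, at 345 bp inside and 227 and 3604 bp outside the gene and at Faf1. The retinoblastoma gene Rb1 had 4, of which 2 lay at Lpar6, and Ccnd3 and Cdk2 had 3 each. The occupied liver genes were Ttr and Fgb, whose peaks lay nearest to B4galt6 and Plrg1. A single peak between Olfr632 and Olfr633 counted for both. The peak counted for Olfr986 lay at Zfp202, and that for Olfr288 lay 4872 bp outside the gene. Peaks near vomeronasal genes were 181 bp from Vmn1r4, 1290 bp from Vmn2r87 and, at the border of AI987944, 6302 bp from Vmn2r57.

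No other list passed the test. Germ cell genes were occupied in 19 of 30 cases (ratio 1.27, permutation adjusted p = 0.367), steroid-producing cell genes in 7 of 20 (0.68, adjusted p = 0.367) and gonadal stroma genes in 8 of 20 (0.73, adjusted p = 0.469). For surface epithelium genes the count was 6 of 14 (0.85, permutation adjusted p = 0.840), for endothelial genes 7 of 16 (0.80, adjusted p = 0.632), for blood genes 3 of 16 (0.47, adjusted p = 0.303) and for mesonephros genes 4 of 10 (0.68, adjusted p = 0.526). Neuron genes were occupied in 6 of 20 cases (0.51, permutation adjusted p = 0.0659). Their ratio was 0.14 for own-border peaks, 0.30 within 5 kb of a border and 0.52 with matching on neighbouring borders, and it then passed (permutation adjusted p = 0.0147, 0.0147 and 0.0438). Among signalling pathways, WNT genes were occupied in 29 of 45 cases (1.09, permutation adjusted p = 0.632), TGF-beta and BMP genes in 28 of 42 (1.19, adjusted p = 0.367), Notch genes in 18 of 25 (1.32, adjusted p = 0.303) and hedgehog genes in 12 of 16 (1.25, adjusted p = 0.526). Nuclear receptor genes were occupied in 28 of 41 cases (1.14, permutation adjusted p = 0.526), basement membrane genes in 17 of 25 (1.02, adjusted p = 1), forkhead genes in 23 of 44 (1.14, adjusted p = 0.572), Sox genes in 12 of 19 (1.45, adjusted p = 0.303) and Gata genes in 4 of 6 (1.18, adjusted p = 0.975). With peaks assigned to the nearest border, the TGF-beta and BMP list (1.48, permutation adjusted p = 0.0071) and the forkhead list (1.5, adjusted p = 0.0312) passed.

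**Figure D3:**
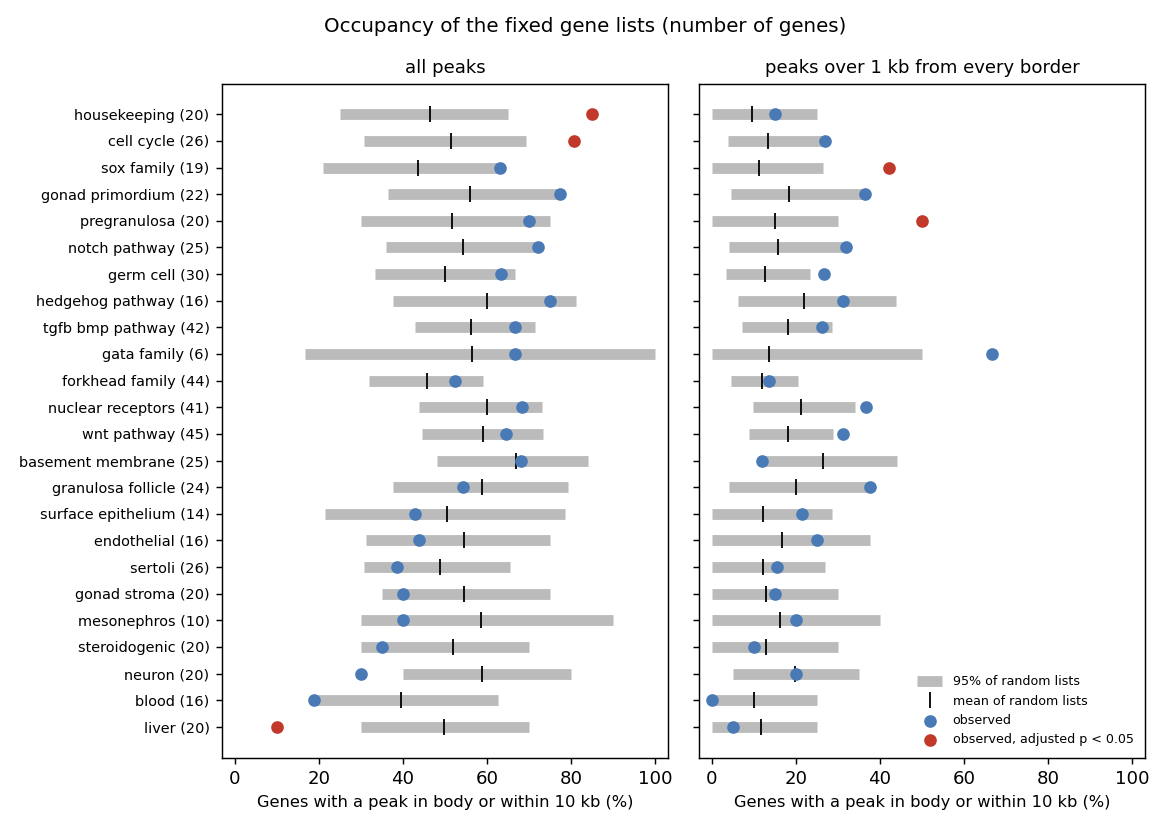
Percent of genes occupied by a FOXL2 peak (horizontal axis) for each gene list except the olfactory and vomeronasal receptors (vertical axis, number of genes in brackets), for all peaks and for peaks over 1 kb from every border; bars span 95% of length-matched random lists, ticks mark their mean, and red points passed the test. Pregranulosa genes lie at 70.0% for all peaks and at 50% for peaks away from borders.

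Some genes had several peaks in their window, where peaks of neighbouring genes are counted as well. Of the occupied genes, 7612 had 1 peak, 2630 had 2, 528 had 3 and 69 had 4. Snd1 had the most, with 8 peaks inside the gene, of which 1 lay at the border of the nested gene Lrrc4. The adhesion receptor gene Adgrl3 and the transcription factor gene Sox5 had 7 each, all inside the gene, and 6 of those in each gene lay over 1 kb from every border. Skida1, Srrm2, Fto and Camta1 had 6 peaks, and Fam120a, the homeobox gene Meis1, the chromatin remodeller gene Chd7, Hivep2, Map3k5, Tead1, Pitpnc1 and Maml3 had 5. Relative to length, Skida1 was densest with 2.46 peaks per 10 kb of window, none of them inside the gene. Cdkn2c (1.55), Eno3 (1.36) and the Polycomb gene Bmi1 (1.35) came next among genes with at least 4 peaks. Many of these peaks lay nearest to other genes. Some of the Skida1 peaks were nearest to Mllt10. The peaks outside Eno3 were nearest to Rnf167, Slc25a11 and Camta2, and those outside Bmi1 to Commd3, Gm46725 and Spag6. Zfp771, Ddx39b, Srrm2, Dedd, Ppm1g, Nr4a1, Nrbp1, Rabepk, Zfp777, Mtarc2 and Eef1akmt4-ece2 followed, from 1.25 for Zfp771 to 0.736 for Eef1akmt4-ece2. Ppm1g and Nrbp1 shared the peaks at the border of Ppm1g. A neighbouring peak within 10 kb was found for 2449 peaks (21.4%), against 8.86% under random placement, 2.42 times chance (permutation p = 0.002, two-sided, the smallest possible). When border peaks were placed at random borders of the same chromosome instead, an option added after the data were examined, placed peaks had a neighbour in 22.9% of cases and the ratio was 0.936 (permutation p = 0.002). Those borders were drawn with repeats and without the least spacing of 355 bp seen among real centres. Both can raise the placed share, so this ratio does not show that peaks avoid each other. Windows of 2 or more genes shared 30.9% of peaks, and 1213 peaks lay in no gene's window.

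Peaks were sparse on the X chromosome. It held 310 peaks, or 1.82 per Mb, against 4.63 ± 0.971 per Mb (SD, n = 19) on the autosomes, a ratio of 0.393. All 19 autosomes lay above it, from 3.45 per Mb on chromosome 14 to 7.37 on chromosome 11 (exact two-sided rank p = 0.1, the smallest that 19 autosomes allow). The X chromosome also held fewer protein-coding genes, 5.66 per Mb against 8.56 ± 2.5 (SD, n = 19). Chromosome 12, the autosome with the lowest gene density (5.66 per Mb), held 3.75 peaks per Mb. Per protein-coding gene X had 0.321 peaks against 0.555 ± 0.0714 on the autosomes, where chromosome 7 was lowest with 0.354. Peaks over 1 kb from every border numbered 0.627 per Mb on X against 1.69 ± 0.315 on the autosomes, where chromosome 16 was lowest with 1.27. A single peak lay on the Y chromosome, in tissue labelled XX. Across the 19 autosomes, peak density followed gene density (Pearson r = 0.847, Spearman rho = 0.925, each permutation p = 1e-05, the smallest that 100000 permutations give). Without chromosomes 11 and 7, the farthest from the median density, r was 0.938. This was the single correlation computed.

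**Figure D4:**
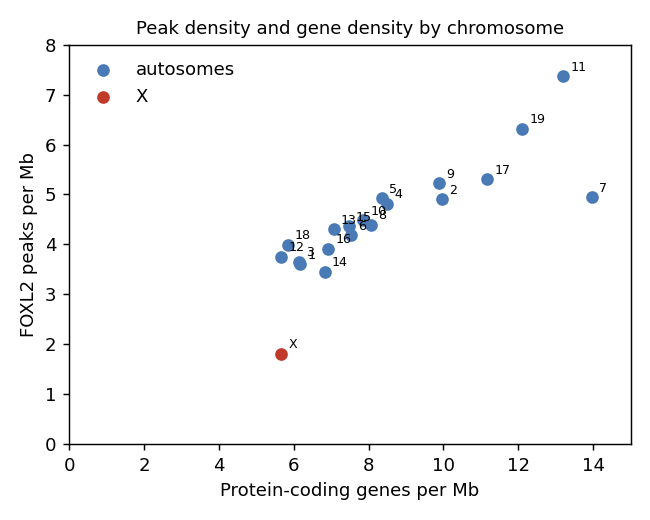
FOXL2 peaks per Mb (vertical axis) against protein-coding genes per Mb (horizontal axis) for the 19 autosomes and the X chromosome, each point labelled with its chromosome. X lies at 1.82 peaks per Mb, below every autosome.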

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

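Peaks moved by up to 1 Mb, odd and even autosomes, peaks per gene, peaks over 1 kb from every border, own-border peaks, matching on neighbouring borders and random borders were settings chosen after the data were examined. The excess at gene borders and within 10 kb of them, and the low density on X, kept direction in all settings run, though each p was the smallest its test can give, which shows no stability, with ratios of 5.75 to 22.2 at borders, 2.43 to 3.64 within 10 kb and 0.371 to 0.578 on X. Clustering kept its direction (1.62 to 3.20) except with border peaks placed at random borders, drawn with repeats, where the ratio was 0.936. Lists called higher numbered 2 in the main analysis, 6 with the nearest border and 4 with neighbour matching. Lists called lower numbered 3 in the main analysis, 5 with own-border peaks, 4 within 5 kb of a border, 4 with neighbour matching, 2 in a 50 kb window and 2 for peaks over 1 kb from every border. With the nearest border, ratios were 1.87 for pregranulosa and 2.0 for early gonad genes, which then passed, and 1.08 for later granulosa, 1.15 for stroma, 1.25 for surface epithelium, 1.09 for endothelial, 1.01 for mesonephros and 0.921 for basement membrane genes, which turned without passing. With neighbour matching, pregranulosa (1.68) and early gonad genes (1.49) passed, and later granulosa (1.01) and basement membrane genes (0.997) turned. In a 50 kb window, later granulosa (1.0), Sertoli (1.06), surface epithelium (1.1), endothelial (1.14), mesonephros (1.19) and hedgehog genes (0.995) turned. Within 5 kb of a border, germ cell (0.990) and Gata genes (0.657) turned. With peaks over 1 kb from every border, pregranulosa genes passed (3.31), and later granulosa (1.88), Sertoli (1.25), stroma (1.16), surface epithelium (1.75), endothelial (1.5), mesonephros (1.24), neuron (1.01) and basement membrane genes (0.455) turned. With own-border peaks, later granulosa genes passed as lower (0.336), and pregranulosa (0.936), nuclear receptor (0.841) and Gata genes (0.0) turned. No list that turned had passed in the main analysis. The cause of these changes was not tested. Of the other values under alternatives, 24 for the main results and 102 for the remaining lists kept their direction and side of the threshold, and 9 counts of called lists stayed within 1.5 times the main count. No paired analysis was possible because the list holds no values per sample, although ChIP and input share replicate numbers. For the same reason ChIP was not set against input and no replicate was left out. A stricter subset of the peaks, GC-matched placement, masked repeats, promoter GC matching and the motif tests were not run. The unknown read depth limits every statement about unoccupied genes.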

Other observations

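The symbol families, the Sox, Gata and Hox genes away from borders, the X density without receptor genes and the regulator families without Hox genes were tests chosen after the result was seen. Genes were grouped by shared symbol stem into 165 families of at least 15 genes, of which 36 were occupied more often and 38 less often than length-matched genes (permutation test with Benjamini-Hochberg adjustment). With peaks over 1 kb from every border alone, 4 were higher and 5 lower, and of the families named here as higher the Rpl genes alone passed (ratio 3.19, permutation adjusted p = 0.033). Among those occupied more often, of the Rpl genes of the large ribosomal subunit 44 of 53 were occupied (83.0% against 34.8%), of the mitochondrial Mrpl genes 44 of 49, of the Mediator Med genes 27 of 30, of the RNA-binding Rbm genes 35 of 38 and of the Integrator Ints genes 15 of 15. Dusp phosphatase genes were occupied in 21 of 24 cases. Among those occupied less often, none of 26 Klk, 25 Prl, 24 Serpina, 42 Defb and 22 Mup genes was occupied, and cytochrome P450 genes were occupied in 12 of 99 cases (12.1% against 53.3%), keratins in 8 of 53, interleukin genes in 19 of 83 and collagen genes in 18 of 44 (40.9% against 65.0%). Many of these families sit in clusters whose genes share windows, so their members are not independent.

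Sox genes were occupied away from borders in 8 of 19 cases, against 11.2% in matched lists, a ratio of 3.75 (permutation adjusted p = 0.0065). Sox5 had 6 such peaks, Sox4, Sox12 and Sox30 had 2 each, and Sox1, Sox2, Sox6 and Sox17 had 1 each. The nearest lay 1036 bp (Sox30), 1185 bp (Sox17), 1299 bp (Sox12) and 1680 bp (Sox4) inside the gene, where the border excess continues. Those of Sox1, Sox2, Sox5 and Sox6 lay farther from the border. The Gata list had 4 of 6 genes occupied away from borders (Gata3, Gata4, Gata5 and Gata6, ratio 4.9, permutation adjusted p = 0.0551), and none of the 6 at its own border. Of 39 Hox genes 19 (48.7%) had a peak away from borders in their window, and neighbouring Hox genes share peaks. Of the peaks away from borders, 10.7% had another within 10 kb against 3.31% of placed ones, a ratio of 3.23 (permutation p = 0.002, the smallest possible). Random placement does not follow genes. For all peaks the ratio was 2.42 with random placement, 1.63 with moves of up to 1 Mb and 0.936 with border peaks placed at random borders. The value of 3.23 therefore does not separate clustering of these peaks from the positions of genes.

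Housekeeping genes were occupied more often than length-matched genes (17 of 20, ratio 1.83). Peaks of neighbouring genes in gene-dense regions were argued against as the whole account, since the ratio was 1.72 once random lists were also matched on neighbouring borders (permutation p = 0.0012). Occupancy at borders alone was tested on 344 genes of ubiquitous families, set by symbol. Their own borders were occupied in 59.0% of cases against 26.4%. Their occupancy by peaks over 1 kb from every border was also raised, with a ratio of 1.56 (permutation p = 0.0008). That class holds the edge of the border excess, with 96 peaks 1000 to 1100 bp inside genes against 16.6 placed, so the test cannot decide. In the housekeeping list itself 3 of 20 genes had such a peak (ratio 1.56, permutation adjusted p = 0.777). Open chromatin being recovered without FOXL2 may also give such a pattern, was not tested because no values of the input samples were analysed here, and stays open, as no biological explanation was tested either.

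The X chromosome held fewer peaks per Mb than any autosome. A lower number of genes was left open, since X had 0.210 border peaks per gene (95% Poisson limits 0.182 to 0.241) and the lowest autosome, chromosome 7, 0.225. Without olfactory and vomeronasal receptor genes X had 0.212 (0.184 to 0.243) and the lowest autosome 0.283. Those families were left out after their low occupancy was seen. Chromosome 7 went from 2030 to 1613 genes and X from 966 to 959. The step could hardly change X, so the wider gap does not separate gene number from the kinds of gene on X. Lower recovery over all kinds of site goes with the 0.627 peaks per Mb away from borders, below all 19 autosomes. That density is not adjusted for genes, although 2522 of those 4190 peaks over all chromosomes lay inside genes. X held 5.66 genes per Mb against 8.56 on the autosomes, and chromosome 12, also at 5.66, had 1.42 such peaks per Mb. Gene number or gene content could also lower the value on X, so it does not single out lower recovery. The gene content of X stays open, because ubiquitous genes had a peak at their own border in 5 of 11 cases on X and 198 of 332 on autosomes, a ratio of 0.762 (Fisher's exact p = 0.366). Inactivation of an X chromosome in XX somatic cells is a biological candidate that these positions did not test.

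Pregranulosa genes had a peak away from every border more often than length-matched genes (10 of 20, ratio 3.31). Sp5 and Fst were counted through a peak 1319 and 1604 bp inside the gene, where the border excess continues. There, 68 peaks lay 1300 to 1400 bp inside genes against 16.3 placed, and 41 lay 1600 to 1700 bp inside against 16.0. Matched lists were counted by the same rule, but the 10 of 20 may include peaks of the border excess. A scarcity of neighbouring borders was argued against, since matching on them gave a ratio of 3.47 (permutation p = 0.0002, the smallest possible). Regulator genes of other tissues had a ratio of 2.63 as well (27 of 112), which is consistent with a property of developmental regulators of any tissue. Without the Hox genes, whose clusters share peaks and which gave 19 of the 27, it was 8 of 73 (11% against 10.1% expected, ratio 1.08, permutation p = 0.918; Fisher's exact p = 0.000382 against the pregranulosa share), but they were left out after their values were seen and Sox genes reached 42.1%, so this excludes nothing. Whether the peaks are tied to the supporting cells stays open, since none of the 10 comparisons between fixed lists passed adjustment and no biological explanation was tested.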
